A study of Arabidopsis thaliana with 8 samples.

How the data were processed

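The series holds poly(A) RNA-seq of whole rosettes of Arabidopsis thaliana, accession Col-0. The plants were 17 days old and had not bolted. Each library was made from a pool of 5 plants with a directional kit, per the labels' protocols. There were 4 libraries of the wild type and 4 of the double mutant hta9 hta11. The groups were taken from the genotype label of each sample and the replicate numbers from the sample titles. The protocol text speaks of fewer replicates per genotype than the 4 the labels list; all 8 libraries were used. The labels describe pools of separate plants, so the spread between libraries includes variation between pools.

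The authors deposited 1 table of whole-number counts per gene, with 36796 gene identifiers and a column per library, matched to the samples by the library names. Per the submitters' processing notes, fastp 0.23.2, HISAT2 2.2.1, SAMtools 1.17, DESeq2 and limma were used with the build TAIR10. The counting program, its strand setting and its treatment of reads that map to several places are not given in the sources used here. Counts of genes that overlap, of antisense partners and of near-identical copies are therefore uncertain, and this applies to tandem or close paralogs such as MAF4 and MAF5, LSU1 and LSU3, KIN1 and its neighbour, the LHCB1 genes and the AT4G22485 family. The labels do not give the kind or position of the mutations, so reads of HTA9 and HTA11 in the mutant need not come from complete transcripts. Of the table's columns of values, 0 were left unused.

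Library totals ran from 31611735 to 47467130 counts, with a median of 37580069. Chloroplast genes took 0.421% to 0.755% of the counts in a library, and the 10 most abundant genes took 7.02% to 8.43%. Within each genotype every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of 12.5 to 45.3 over genes with at least 20 counts, so no library was counted as a repeat of another. Gene names, gene types and positions came from the RefSeq annotation of TAIR10.1, in which 36632 identifiers were found. The 164 others were organelle genes. Positions are given on TAIR10.1.

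Genes were filtered with filterByExpr and scaled with TMM in edgeR 4.0.16 under R 4.3.3, which left 20214 genes for testing; 9986 genes had no count in any library. The main test was edgeR's quasi-likelihood F test of genotype on the counts as deposited, over all 8 libraries, 2-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. All adjusted p-values of single genes come from this test unless another is named. Standard errors were derived from the log2 fold change and the F statistic. CPM values were computed on TMM-scaled library sizes and are given as mean ± SD over 4 libraries. Positive log2 fold changes mean higher in hta9 hta11. A second count required a change of at least 2-fold. The design was fixed before the data were examined, together with 24 gene lists of 334 members, the alternatives and the rule for named genes.

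The lists were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, for lists with at least 3 tested members, adjusted over the 22 lists tested. Of the members, 3 were dropped because the reference names disagreed with their identifiers, and 1 was not in the table. For each list the number of members that passed is given over all genes tested and adjusted over the list alone.

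The rule for named genes took HTA4, HTA8, HTA9, HTA11, FLC, MAF4, MAF5, FT, SOC1 and PR1. Leaving out these, it then took the 12 largest rises and the 12 largest falls among genes that passed, had a mean of at least 1 CPM over all 8 libraries and showed no overlap between the groups. From each list it took up to 4 members that passed, by the size of their change, or up to 2 with the highest mean CPM where none passed. Other genes named in the text were chosen after their values were seen, which is said where they appear.

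The test was checked on simulated data drawn from the means and library sizes of these 8 libraries, for the comparison of hta9 hta11 with wild type. Among 20090 genes tested, with 200 changed, 82% of the 100 genes changed by 1 on the log2 scale and 97% of the 100 changed by 2 were recovered, with 7 false calls. Each gene was drawn independently, so the simulation lacked the variation that genes share across these libraries. Its rates need not hold for the real data.

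The alternatives were RLE and upper-quartile scaling, no count filter, a stricter filter of at least 1 CPM in at least 4 libraries, the replicate number as a block, nuclear genes only, each library left out in turn, DESeq2 1.42.0, limma-voom, an adjusted p under 0.01, and for the lists an estimated inter-gene correlation and fry. A pair of alternatives was chosen after the data had been examined. The first left out hta9 hta11 libraries 1 and 3. The second added the first principal component of the deviations from the genotype means as a covariate.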

Results

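The data were 8 RNA-seq libraries of whole rosettes, 4 from wild-type plants and 4 from plants of the genotype hta9 hta11. HTA9 and HTA11 encode H2A.Z, a histone variant that replaces H2A in nucleosomes near transcription start sites, and the comparison asks how transcript levels differ in plants with these genes mutated. Library totals were 32027511 to 40635454 counts in the wild type and 31611735 to 47467130 counts in hta9 hta11. The first principal component held 42.8% of the variance. It separated the genotypes, with the wild type between -34.3 and -17.1 and hta9 hta11 between 2.51 and 40.9, where 2.51 belonged to hta9 hta11 library 1.

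In hta9 hta11 rosettes that had not bolted, repressors of flowering were lower and floral identity genes were higher than in the wild type. Many genes that were almost silent in the wild type rose, and genes of the sulfur deficiency response fell. The targeted genes were lower in hta9 hta11 but not at the same level in its 4 libraries. HTA9 (AT1G52740, chromosome 1, 19645236 to 19646485) had 95.3 ± 8.05 CPM in the wild type and 31.3 ± 21.3 CPM in hta9 hta11 (SD, n = 4), a log2 fold change of -1.60 (SE 0.38, adjusted p = 0.0457). HTA11 (AT3G54560, chromosome 3, 20196140 to 20197726) had 44.9 ± 6.73 CPM and 11.7 ± 10.8 CPM, a log2 fold change of -1.93 (SE 0.56) that did not pass the threshold (adjusted p = 0.0924). Libraries 2 and 4 held 14.8 and 16.5 CPM of HTA9 and 2.98 and 3.60 CPM of HTA11. Library 1 held 60.6 and 26.0 CPM and library 3 held 33.4 and 14.1 CPM of the same genes, so in both genes the 4 mutant libraries lay below the 4 wild-type libraries. The wild-type libraries ranged from 86.0 to 103.9 CPM for HTA9 and from 38.5 to 54.1 CPM for HTA11. HTA8, a further H2A.Z gene, had 16.4 ± 1.83 CPM in the wild type and 17.95 ± 3.002 CPM in hta9 hta11 (adjusted p = 0.665), and HTA4 had no count in any library.

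**Figure D1:**
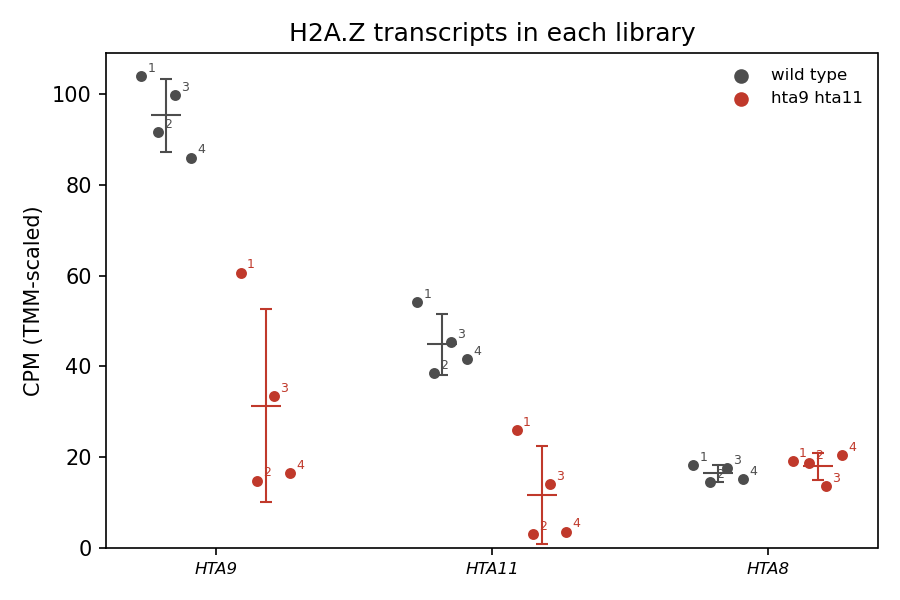
CPM of the H2A.Z genes HTA9, HTA11 and HTA8 in each library, with the replicate number beside each point and the mean and SD of 4 libraries as bars. In hta9 hta11, HTA9 was at 60.6 CPM in library 1 and 33.4 CPM in library 3 against 14.8 and 16.5 CPM in libraries 2 and 4.

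As a list, the H2A.Z genes were lower (3 tested, 1 passed, 2 adjusted over the list alone; camera adjusted p = 0.0282), with an adjusted p = 0.37 with an estimated correlation and 0.0916 without hta9 hta11 library 3. Of the 3 tested members, HTA9 and HTA11 are the genes mutated in this genotype, so the list's fall was built in. The HTA9 call ended without any single wild-type library or without hta9 hta11 library 2, 3 or 4, with an adjusted p of up to 0.123 without library 4. The HTA11 change passed without hta9 hta11 library 1 (log2 fold change -2.73, adjusted p = 0.0103), and without libraries 1 and 3, which were left out for their levels of these genes, the log2 fold changes were by construction larger, at -2.61 for HTA9 and -3.77 for HTA11.

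Between the genotypes 757 of 20214 genes changed, 504 higher and 253 lower in hta9 hta11, which is 3.74% of those tested. Of these, 309 changed at least 2-fold, 251 upward and 58 downward. Genes that rose were poorly expressed in the wild type, with a median of 1.96 CPM, against 22.9 CPM for genes that fell and 15.1 CPM for all tested genes. Of 2008 tested genes with a wild-type mean below 1 CPM, 185 rose and 6 fell. Part of this imbalance is built into the choice of genes. The count filter kept genes expressed in either group, and a gene almost silent in the wild type has little room to fall. Of 102 organelle genes tested, 0 passed in edgeR and in limma-voom and 1 in DESeq2, with 1 at an unadjusted p under 0.05. Of the 757 genes, 747 showed no overlap between the groups, as did 11.3% of all tested genes, where chance gives 2.86%. The count of changed genes moved by more than 1.5 times with the libraries used. It was 1246 without hta9 hta11 library 1, 293 without library 2, 208 without library 4 and 395 to 472 without any single wild-type library. The count of genes changed at least 2-fold was 187 without hta9 hta11 library 2 and 151 without library 4.

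**Figure D2:**
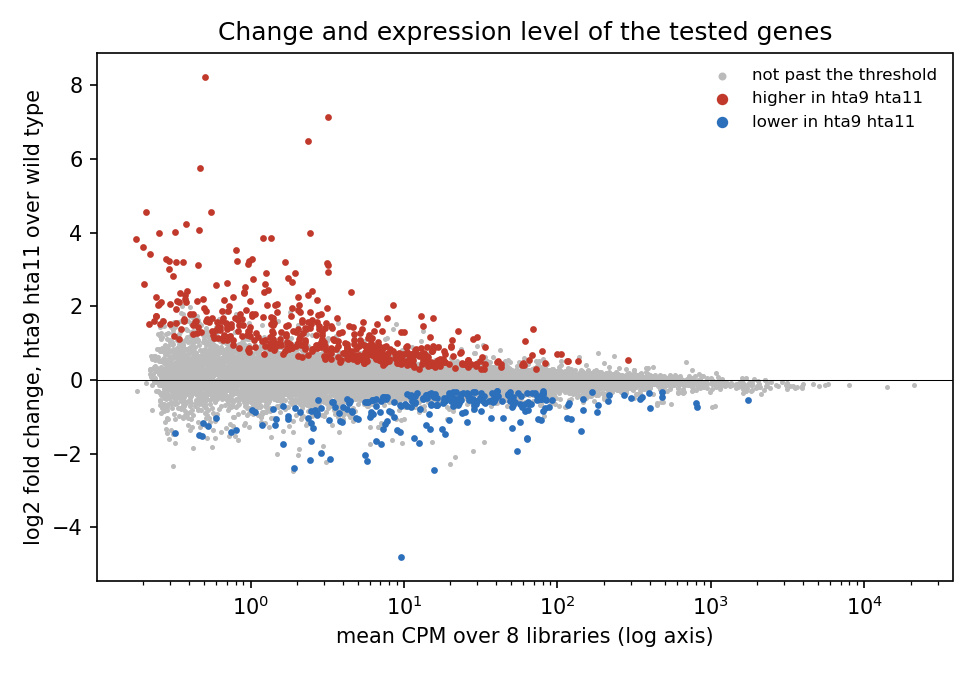
Log2 fold change of hta9 hta11 over wild type against the mean CPM over 8 libraries on a log axis, 1 point per tested gene. Red points are the 504 genes that were higher and blue points the 253 genes that were lower at an adjusted p under 0.05 in edgeR's test.

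The repressors of flowering were lower in hta9 hta11 and a set of flowering activators was higher. Of 13 flowering time repressors tested, 3 fell and none rose (5 fell adjusted over the list alone; camera adjusted p = 8.1e-13), and the list also passed with an estimated correlation (adjusted p = 0.0469). MAF5, a MADS-box repressor of flowering (AT5G65080, chromosome 5, 25997504 to 26002619), showed the deepest fall of all named genes, from 18.6 ± 4.06 to 0.664 ± 0.308 CPM (log2 fold change -4.79, SE 0.28, adjusted p = 7.7e-05). Its neighbour MAF4 fell from 3.78 ± 0.495 to 1.201 ± 0.269 CPM (log2 fold change -1.66, adjusted p = 0.0024). FLC, the central repressor in the vernalization pathway (AT5G10140, chromosome 5, 3173382 to 3179448), fell from 5.38 ± 1.00 to 1.23 ± 0.479 CPM (log2 fold change -2.13, SE 0.26, adjusted p = 0.00322). The related genes FLM, MAF2 and MAF3 did not pass, with log2 fold changes of -0.23, -0.08 and -0.01, the last of which was 0.01 with upper-quartile scaling. FLM, MAF2 and MAF3 were chosen after their values were seen.

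Of 13 flowering time activators tested, 3 rose and none fell (8 rose adjusted over the list alone; camera adjusted p = 6.1e-08, adjusted p = 0.0469 with an estimated correlation). FUL, a MADS-box gene active in the shoot meristem at the floral transition, rose from 5.74 ± 0.679 to 14.3 ± 3.33 CPM (log2 fold change 1.32, adjusted p = 0.0038). FD, the bZIP partner of the florigen FT, rose from 3.02 ± 0.241 to 5.54 ± 0.713 CPM (log2 fold change 0.88, adjusted p = 0.00656). SOC1, a floral integrator that FLC represses, rose from 33.6 ± 3.34 to 48.6 ± 2.87 CPM (log2 fold change 0.53, adjusted p = 0.0105). FT had 1.24 ± 0.502 and 2.39 ± 0.618 CPM and did not pass (log2 fold change 0.95, SE 0.29, adjusted p = 0.109), although it passed without wild type library 1 (log2 fold change 1.25, adjusted p = 0.0466) and in DESeq2 (adjusted p = 0.0312), within a range of 0.0312 to 0.284 over its alternatives.

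A mixed list of floral and other developmental genes under Polycomb repression had the smallest p in camera at the preset correlation, while with an estimated correlation and in fry the flowering repressors did. Of the 18 genes of this list tested, 9 rose and none fell (15 rose adjusted over the list alone; camera adjusted p = 4.1e-20, adjusted p = 0.0469 with an estimated correlation). The list was at a median log2 fold change of 1.23. Divided after the values were seen, its 10 floral identity genes (7 rose) had a median of 1.83 (camera p = 1.6e-18, p = 0.00256 with an estimated correlation) and its 8 other members, STM, KNAT1, KNAT2, KNAT6, CUC1, CUC2, PHE1 and AGL19 (2 rose), 0.42 (camera p = 5.8e-07, p = 0.0207 with an estimated correlation). SEP3, which forms complexes with the other floral organ identity factors, rose from 0.744 ± 0.0921 to 5.66 ± 1.70 CPM (log2 fold change 2.92, SE 0.24, adjusted p = 0.000846). SEP2 (AT3G02310) rose from 0.128 ± 0.0554 to 1.47 ± 0.610 CPM (log2 fold change 3.53), AP3 from 0.194 ± 0.0409 to 1.22 ± 0.521 CPM (2.64) and PHE1, a type I MADS-box gene, from 0.341 ± 0.115 to 2.13 ± 0.499 CPM (2.62). AP1, PI, SEP1, SEP4 and CUC1 were the other members that rose, with log2 fold changes of 2.04, 2.18, 1.63, 0.32 and 1.59. These members and the next 3 were named after their values were seen. AG did not pass at -0.49 (adjusted p = 0.301), nor did STM at 0.26 or LFY at 1.22 (adjusted p = 0.143). Without hta9 hta11 library 4 the calls of AP1, PI and CUC1 ended, with adjusted p-values of 0.061, 0.103 and 0.091. AP1 also lost it without wild type library 2, PI without wild type library 2, 3 or 4 or hta9 hta11 library 2, and CUC1 without wild type library 1, 2 or 3 or hta9 hta11 library 2. SEP4 passed in none of the fits without 1 library but that without hta9 hta11 library 1, with an adjusted p of up to 0.127 without hta9 hta11 library 2.

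**Figure D3:**
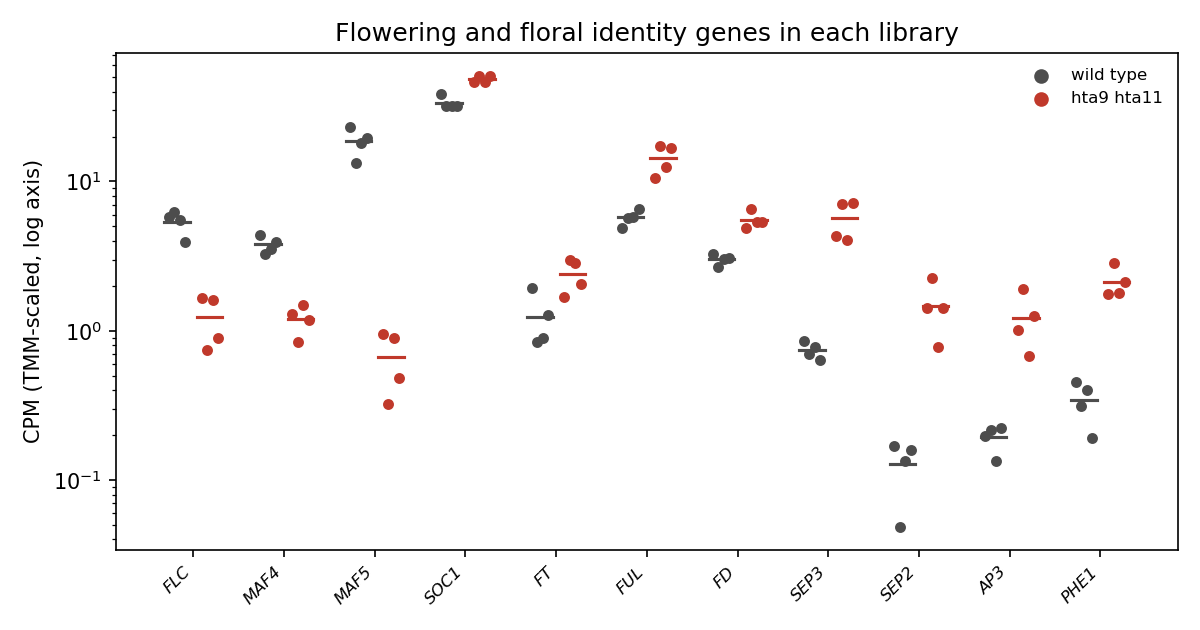
CPM of flowering time and floral identity genes in each library on a log axis, grey for the wild type and red for hta9 hta11, with the mean of 4 libraries as a bar. FLC, MAF4 and MAF5 were lower in all 4 hta9 hta11 libraries, and SOC1, FUL, FD, SEP3, SEP2, AP3 and PHE1 were higher.

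Few chromatin genes on the fixed lists passed. Of 22 genes for H3K27me3 writers, readers and erasers, 0 passed in edgeR, DESeq2 or limma-voom and 3 had an unadjusted p under 0.05 (0 adjusted over the list alone; camera adjusted p = 0.911), with JMJ30 at 182 and 181 CPM and PKL at 74.9 and 79.9 CPM in wild type and hta9 hta11. Of 11 genes of the SWR1 complex, which exchanges H2A for H2A.Z, and its partners, 0 passed in edgeR, DESeq2 or limma-voom and 1 had an unadjusted p under 0.05 (0 adjusted over the list alone; camera adjusted p = 0.958). ARP4 was at 41.2 and 41.4 CPM and SWC4 at 39.4 and 34.0 CPM (adjusted p = 0.194). Of 9 other histone H2A genes, HTA12 fell (8.42 ± 1.03 to 5.67 ± 0.802 CPM, log2 fold change -0.56, adjusted p = 0.0431) and the list did not pass (1 fell adjusted over the list alone; camera adjusted p = 0.911). The HTA12 call ended without wild type library 1, 3 or 4 or hta9 hta11 library 2, 3 or 4, with an adjusted p of up to 0.124 without hta9 hta11 library 2. Of 3 tested genes tied to DNA methylation, 0 passed in edgeR and limma-voom and 1 in DESeq2, with 1 at an unadjusted p under 0.05 (1 rose adjusted over the list alone; camera adjusted p = 0.958). The list's median and mean log2 fold changes of -0.05 and -0.40 had the opposite sign to camera's direction, which was up. QQS, an orphan gene with variable methylation, held 40.4 to 61.7 CPM in the wild type and 37.0, 1.89, 23.0 and 0.97 CPM in hta9 hta11 libraries 1 to 4 (log2 fold change -1.68, adjusted p = 0.312). ROS1, a DNA demethylase, was at 59.7 and 85.4 CPM (adjusted p = 0.0639) and passed without hta9 hta11 library 1 (log2 fold change 0.60, adjusted p = 0.0264) but not without any other single library. Without hta9 hta11 libraries 1 and 3, a setting chosen after the data were examined, this list was lower (camera adjusted p = 8.3e-05), with QQS at -5.14 (adjusted p = 0.000118) but ROS1 higher (0.57, adjusted p = 0.0849). No estimated correlation was run in that setting.

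Leaving out the genes always named, the 12 largest rises were of genes with little or no transcript in the wild type. AT1G75945, which encodes an uncharacterized protein, rose from 0.0414 ± 0.0265 to 6.31 ± 1.81 CPM (6 counts in the 4 wild-type libraries together, log2 fold change 7.14, SE 0.38, adjusted p = 4.8e-05). AT5G22430, of the pollen Ole e 1 and extensin family, rose from 0.0522 ± 0.0633 to 4.69 ± 2.30 CPM (log2 fold change 6.5, SE 0.66). The Argonaute genes AGO5 and AGO9, known for small RNA pathways of germline tissue, rose 16.3-fold and 7.48-fold, to 4.59 ± 1.93 and 3.46 ± 1.06 CPM. The carboxypeptidase-like gene scpl17 rose 15.2-fold and ADF8, for an actin depolymerizing factor, 10.01-fold. A pair of adjacent genes for HSP20-like proteins on chromosome 5, AT5G47590 (19297614 to 19299174) and AT5G47600 (19299717 to 19300503), rose 9.05-fold and 9.37-fold. CRK23, a cysteine-rich receptor-like kinase, rose 8.77-fold, the cupin gene AT4G36700 7.64-fold, SEP3 7.61-fold and the F-box gene AT5G60610 6.86-fold. AT4G36700 lost its call without any single wild-type library or hta9 hta11 library 2 or 4, with an adjusted p of up to 0.095 without hta9 hta11 library 4. Its log2 fold change went from 2.90 to 2.13 without hta9 hta11 library 2. That library held 4.95 CPM, against 0.57, 1.39 and 1.99 CPM in hta9 hta11 libraries 1, 3 and 4.

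The 12 largest falls were ranked without the genes always named, among which MAF5, FLC, MAF4 and HTA9 had log2 fold changes of -4.79, -2.13, -1.66 and -1.60. They included a gene cluster, sulfur deficiency genes and growth-related genes. AT4G22485, AT4G22513, AT4G22517 and AT4G22520, members of a lipid-transfer protein family that lie between 11844506 and 11858970 on chromosome 4, fell to 18.6%, 21.8%, 22.0% and 18.9% of the wild-type mean. Their log2 fold changes were -2.44 (SE 0.52), -2.19 (SE 0.51), -2.18 (SE 0.50) and -2.40 (SE 0.49), with adjusted p-values of 0.0324, 0.0444, 0.0415 and 0.0274. Each lost its call without wild type library 2, 3 or 4 or hta9 hta11 library 2 or 4, AT4G22513 and AT4G22517 also without hta9 hta11 library 3, and AT4G22513 also without wild type library 1. The adjusted p reached 0.0979, 0.117, 0.122 and 0.076, in hta9 hta11 library 4's absence for AT4G22513 and library 2's for the others. LSU1, LSU3 and SDI1, which respond to sulfur deficiency, fell by 1.73, 1.98 and 1.66 on the log2 scale. LSU3 went from 4.63 ± 1.42 to 1.15 ± 0.443 CPM (adjusted p = 0.00918). EXO and PHI-1, of the exordium family of growth-related extracellular proteins, fell from 95.01 ± 43.03 to 31.8 ± 7.90 CPM and from 19.1 ± 5.32 to 5.84 ± 1.81 CPM. EXO did not pass without hta9 hta11 library 2 or 4 (adjusted p of up to 0.0643 without library 4). The remaining falls were DREB26, an AP2/ERF transcription factor, at -2.03, and the related genes of unknown function AT3G19680 and AT1G50040 at -1.93 and -1.58.

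Photosynthesis genes were lower as a list by a small amount. Of 22 genes 0 passed in edgeR and limma-voom and 3 in DESeq2, with 6 at an unadjusted p under 0.05 (0 adjusted over the list alone). The list had a median log2 fold change of -0.16 (camera adjusted p = 7.9e-05, adjusted p = 0.693 with an estimated correlation). RBCS1A, for the small subunit of Rubisco, was at 21858.6 ± 1699.5 and 20045.2 ± 1000.5 CPM, and LHCB1.3, for a light-harvesting protein, at 15039.8 ± 2137.6 and 13250.1 ± 1725.5 CPM. Salicylic acid and immunity genes were lower as a list (20 tested, 2 fell, 4 adjusted over the list alone, none rose; camera adjusted p = 0.0213, adjusted p = 0.693 with an estimated correlation). WRKY70, a transcription factor in salicylic acid signalling, fell from 103 ± 16.8 to 57.6 ± 11.01 CPM (log2 fold change -0.83, adjusted p = 0.0153) and WRKY38 from 2.03 ± 0.752 to 0.868 ± 0.135 CPM (log2 fold change -1.22, adjusted p = 0.0345). PR1 was at 4.78 ± 4.85 and 10.3 ± 8.84 CPM (adjusted p = 0.503). The immunity list did not pass without wild type library 3 (adjusted p = 0.168) or without hta9 hta11 library 3 (0.0916) or 4 (0.0595), and WRKY38 and WRKY70 lost their calls without hta9 hta11 library 4 (adjusted p = 0.117 and 0.0659) or 2. WRKY38 also lost it without wild type library 1, 3 or 4 or hta9 hta11 library 3.

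In 6 further lists that did not pass, single members did. Of 15 clock genes, 2 fell (2 adjusted over the list alone; camera adjusted p = 0.0678), namely ELF4 at -0.56 (adjusted p = 0.0201) and CHE at -0.50 (adjusted p = 0.0336). The clock list passed without wild type library 1 (camera adjusted p = 0.0321) or 3 (0.0273), without hta9 hta11 library 2 (0.0126) or 4 (0.0459), with no count filter (0.0403) and with the component of the deviations from the genotype means as a covariate (0.0465), which was chosen after the data were examined. With an estimated correlation over all libraries it was at 0.693. Of 15 cold, drought and abscisic acid genes, 2 rose (2 adjusted over the list alone; camera adjusted p = 0.168, and 0.97 with an estimated correlation). This list passed without wild type library 1 (camera adjusted p = 0.0321) or hta9 hta11 library 2 (0.0051). KIN1, a cold-induced gene, went from 3.44 ± 0.532 to 9.88 ± 1.06 CPM (log2 fold change 1.52, adjusted p = 0.000856) and RD29B from 0.294 ± 0.168 to 1.52 ± 0.415 CPM (2.39, adjusted p = 0.00935). Of 11 senescence genes, ASN1, for asparagine synthetase, rose by 0.85 and SEN1 (AT4G35770) by 1.18 (2 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.958). Of 20 flavonoid and anthocyanin genes, EGL3, a bHLH factor, rose by 0.56 (3 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.911). Of 14 jasmonate genes, JAZ7, for a repressor of jasmonate signalling, fell by 1.73 (adjusted p = 0.0469; 2 fell adjusted over the list alone; camera adjusted p = 0.221). Of 8 heat shock genes, HSP18.2 rose by 0.96 (adjusted p = 0.0326; 1 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.911). Without hta9 hta11 library 4 the calls of CHE, EGL3, HSP18.2 and SEN1 ended, with adjusted p-values of 0.114, 0.0997, 0.112 and 0.0971. JAZ7 reached 0.114 without wild type library 3 and ELF4 0.065 without hta9 hta11 library 2. These calls also ended without hta9 hta11 library 2 for all of them, without library 4 for JAZ7 and ELF4, without library 3 for CHE, EGL3, HSP18.2 and JAZ7, and without wild type library 1 (CHE, EGL3, JAZ7), 2 (EGL3, HSP18.2, JAZ7), 3 (CHE, EGL3, HSP18.2, SEN1) or 4 (CHE, HSP18.2, SEN1).

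In the other lists 0 members passed in edgeR or limma-voom, and in DESeq2 only 1 glucosinolate gene did. At an unadjusted p under 0.05 there were 3 glucosinolate genes, 1 cell cycle gene, 1 gibberellin gene, 1 embryo gene and 0 genes for DNA damage, phosphate starvation or root markers, and 0 of these lists' genes passed adjusted over the list alone except the embryo gene. Glucosinolate genes (19 tested; camera adjusted p = 0.0746) included MAM1 at 340 and 280 CPM and CYP83A1 at 323 and 304 CPM. The glucosinolate list passed without wild type library 1 (camera adjusted p = 0.0321) or hta9 hta11 library 4 (0.0259) and with that component as a covariate (0.0465), and was at 0.657 with an estimated correlation over all libraries. Cell cycle genes (8 tested; camera adjusted p = 0.958) included KNOLLE at 39.6 and 39.0 CPM and CYCD3;1 at 26.9 and 30.0 CPM. DNA damage response genes (10 tested; camera adjusted p = 0.958) included TSO2 at 85.9 and 85.1 CPM and SOG1 at 18.4 and 17.9 CPM. Gibberellin genes (10 tested; camera adjusted p = 0.958) included GID1A at 26.7 and 27 CPM and GA2OX2 at 11.3 and 12.2 CPM. Phosphate starvation genes (12 tested; camera adjusted p = 0.911) included SQD1 at 94.1 and 91.3 CPM and SQD2 at 70.3 and 72.8 CPM. Root markers (3 tested; camera adjusted p = 0.911) included PYK10 at 84.9 and 76.0 CPM and SHR at 16.13 and 18.21 CPM. Of the embryo and seed storage genes only FUS3 was tested, at 0.329 and 0.512 CPM (adjusted p = 0.203; 1 rose adjusted over the list alone), and neither pollen marker had enough counts to be tested.

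**Figure D4:**
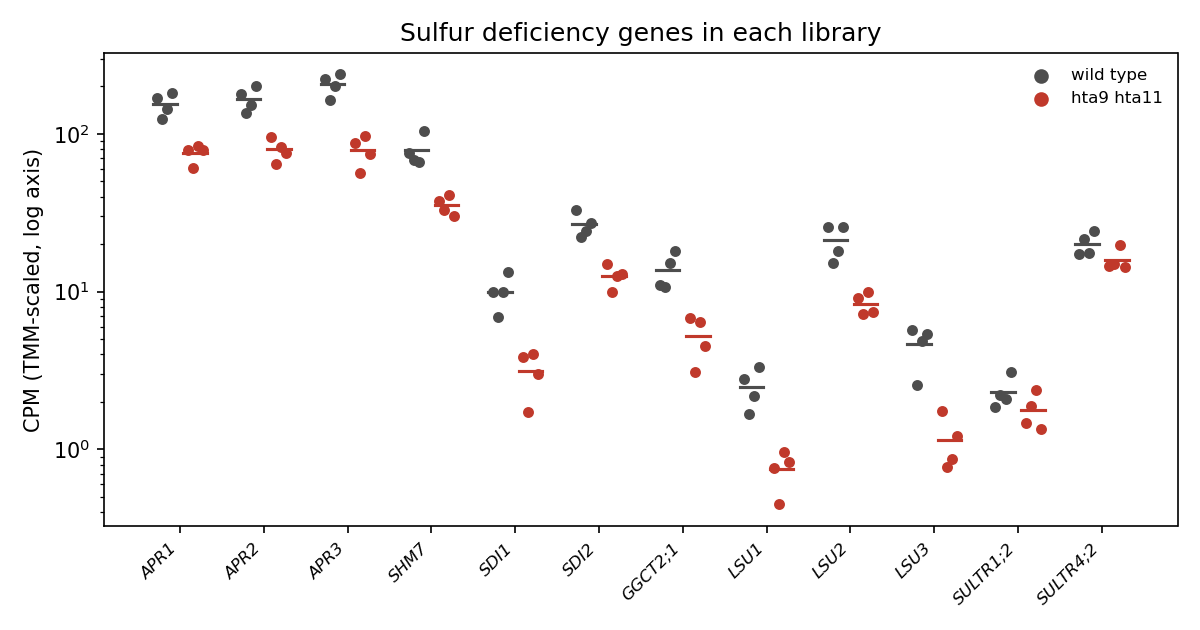
CPM of sulfur deficiency genes in each library on a log axis, grey for the wild type and red for hta9 hta11, with the mean of 4 libraries as a bar. LSU1, LSU3 and SDI1 are among the 12 largest falls, and the other genes of the plot come from a list made after part of its values were seen. The last 2 genes on the axis did not pass. BGLU28, a tested member of the list that was higher in hta9 hta11 and did not pass, is not plotted.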

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

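The mixing tests and the tests of hta9 hta11 libraries 1 and 3 left out were chosen after the result was seen; the splits, the test of a weaker change in library 1 and the floral tests were written before their results were seen, but the floral primordia test was set to undecided afterwards.

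HTA9 and HTA11 transcripts differed between the mutant libraries, with hta9 hta11 library 1 at 60.6 and 26.0 CPM against 14.8 and 2.98 CPM in library 2. Over 96 genes far apart between the wild type and libraries 2 and 4, library 1 lay at a median fraction of 0.482 of the way to wild type (bootstrap interval 0.439 to 0.541), narrowly below the 0.546 that a plain admixture of wild-type plants or RNA needs. The genes went both ways, with 60 of 96 below that bound. Medians were 0.336 for those that fell and 0.514 for those that rose. Single fractions were 0.0301 for MAF5, 0.186 for FLC and 0.723 for QQS. The median thus lay only narrowly on the side against a plain admixture. The interval resamples genes of 1 library that vary together, and the 0.546 is a single HTA11 value without a spread. Their margin therefore cannot decide the question. In library 3 the median of 0.396 lay above the 0.222 of HTA9, which leaves admixture undecided there, although MAF5 lay at 0.0272. A candidate explanation that stays open is partial HTA9 and HTA11 expression going with a weaker change of other genes, since libraries 1 to 4 lay at 0.439, -0.296, 0.275 and -0.179 of the way to wild type, over differing sets of 453, 187, 291 and 151 genes called without the library itself, although an admixture would give this too. Each library was measured from the mean of the other hta9 hta11 libraries, so these values depend on one another and are not separate observations.

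The rise of floral identity genes may reflect floral primordia in the sampled shoots or a loss of repression at Polycomb targets. The floral meristem genes tested had a median log2 fold change of 1.63 over 4 genes, from -0.49 for AG to 2.18 for PI, which met the bound of at least 1 written beforehand. All 4 belong to the list whose rise is in question, as was noticed only afterwards, so this gives no separate support for primordia. STM, KNAT1, KNAT2, KNAT6, CUC1, CUC2, PHE1, AGL19 and FUS3, Polycomb targets, had a median of 0.45 over 9 genes, from -0.17 to 2.62, but all except FUS3 also belong to that list, so this gives no separate evidence on a general loss of repression. Both explanations stay open.

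Other ways to divide the 8 libraries into 4 and 4 show how far the genotype stands out. Of 35 splits, 2 gave at least as many changed genes as the 757 between genotypes, so chance cannot be excluded for that count. The other was wild type libraries 1 and 3 with hta9 hta11 libraries 1 and 4 against the rest, with 2947 genes, which points to a structure of the samples that crosses the genotypes, while the remaining 33 splits gave 0. For changes of at least 2-fold only the genotype split reached 309 genes, against 83 in the highest other split. That is 1 of 35, the smallest share these splits can give, so it argues against chance only to that degree. For the lists chance cannot be excluded, with 16 of 35 splits giving at least the 6 lists and up to 9. With an estimated correlation 1 of 35 splits reached the 3 lists of the genotype split, against 0 lists in the highest other split. The floral, activator, repressor and H2A.Z lists each had their smallest camera p in the genotype split, whereas 11 of 35 splits gave a p as small for photosynthesis and 11 for immunity genes. For the H2A.Z list, which is among the 6, this was built in, since HTA9 and HTA11 are the genes that define the genotype.

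Among 174 groups of 4 libraries checked, 8 held a library far from the other 3 in log2 CPM, where chance gives 8.7. Wild type library 1 was high for SOC1 at 5.27 and ELF4 at 5.97 and low for AT4G22520 at 0.76 and SQD1 at 6.41. Wild type library 3 was high for ADF8 at -1.41 and GA2OX2 at 3.90, wild type library 4 was high for MAM1 at 8.93, and hta9 hta11 library 1 was low for ADF8 at 0.18. No biological explanation was tested for these.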

How the results depend on the processing

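Leaving out hta9 hta11 libraries 1 and 3 and the covariate were chosen after the data were examined. In every setting 0 of the 757 called genes tested there changed sign. These genes were called on the same libraries and 747 showed no overlap between the groups, so this was nearly fixed in advance. The count of changed genes, 757, was 1504 with DESeq2 (850 higher, 654 lower), 2262 with the covariate (1167 and 1095) and 152 at an adjusted p under 0.01 (126 and 26). The covariate was estimated from the same data, so its p-values are too small. The count at 2-fold, 309, was 189 with the stricter filter (142 higher), which tests fewer genes, 481 without libraries 1 and 3 (138 lower) and 123 at 0.01 (102 and 21); lower genes were 88 with DESeq2 and 111 with the covariate. Without 1 library the changed genes ranged from 208 to 1246 (170 to 710 higher, 38 to 536 lower) and the 2-fold ones from 151 to 455 (128 to 325 and 23 to 130). Lists past the threshold were 3 with an estimated correlation and 3 with fry. The deviations of libraries with the same replicate number, 1 to 4, correlated at 0.403, 0.353, -0.275 and -0.195. Libraries 1 and 2 of hta9 hta11 correlated best with their own number. Library 3 correlated best with wild type library 4 (0.419) and library 4 with wild type library 1 (0.213). These mixed values do not settle whether the numbers pair samples. With the replicate block 847 genes changed, 608 of them shared.

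HTA9 was at -1.58 with upper-quartile scaling and -1.59 with the stricter filter, both short of the threshold, and ranged from -2.15 to -1.37 without 1 library. HTA11 passed with the replicate block (-2.38), limma-voom (-2.46) and the covariate (-2.02), and ranged from -2.73 to -1.62 without 1 library. Without libraries 1 and 3, which were left out for their HTA9 and HTA11 levels, its -3.77 was larger by construction and gave no support for the call. Named genes lost their call, at these adjusted p-values, with the replicate block (AT4G22485 0.0502, AT4G22520 0.0581, AT4G22513 0.0649, AT4G22517 0.101, JAZ7 0.0603, SEP4 0.0533), limma-voom (AT4G36700 0.136, AT4G22517 0.063, JAZ7 0.0638, WRKY38 0.0527), the stricter filter (AT4G22513 0.0523, JAZ7 0.0557, HTA12 0.0507), upper-quartile scaling (JAZ7 0.0534, HTA12 0.0572), no filter (SEP4 0.0564) and without libraries 1 and 3 (ELF4 0.0592, HSP18.2 0.065, JAZ7 0.0897, HTA12 0.0854, WRKY38 0.0727, SEP4 0.096). ROS1 gained one with upper-quartile scaling (0.0441), the block (0.0277), DESeq2 (0.00987), the covariate (0.000873) and without hta9 hta11 library 1 (0.0264). QQS gained one without libraries 1 and 3 (0.000118) and SWC4 with the covariate (0.0353). Genes that did not pass changed sign with upper-quartile scaling (KNOLLE 0.00118, TSO2 0.00692, JMJ30 0.0084, MAF3 0.0143) and without libraries 1 and 3 (TSO2 0.0279, JMJ30 0.0386, ARP4 -0.00813, DIC2 0.101, MAF3 0.0322). Without 1 library they ranged as KNOLLE -0.0814 to 0.0528, TSO2 -0.0801 to 0.0647, SOG1 -0.154 to 0.00948, GID1A -0.0327 to 0.0469, CYP83A1 -0.153 to 0.0378, JMJ30 -0.0562 to 0.019, SQD1 -0.127 to 0.012, PYK10 -0.288 to 0.025, ARP4 -0.00957 to 0.0234, ZAT10 -0.0874 to 0.431, DIC2 -0.225 to 0.212, SPL5 -0.0195 to 0.103, MAF2 -0.178 to 0.0395, MAF3 -0.0518 to 0.0296 and SMZ -0.242 to 0.0716. The cause was not tested.

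With fry the H2A.Z (0.0726), photosynthesis (0.219) and immunity (0.329) lists did not pass, nor did immunity without libraries 1 and 3 (0.082). Lists that did not pass changed direction at these adjusted p-values: with the stricter filter cell cycle 0.984, DNA damage 0.974 and gibberellin 0.974; with the covariate cell cycle, DNA damage and SWR1 0.962; DNA damage with the replicate block 0.997 and fry 0.994; senescence with upper-quartile scaling 0.99 and no filter 0.918; and without libraries 1 and 3 DNA damage and senescence 0.955 and DNA methylation 8.3e-05. Without 1 library the adjusted p ranged from 0.784 to 0.998 (cell cycle), 0.888 to 0.998 (DNA damage, DNA methylation), 0.268 to 0.974 (flavonoid), 0.876 to 0.998 (gibberellin), 0.448 to 0.983 (H3K27me3), 0.606 to 0.981 (heat shock), 0.468 to 0.988 (other H2A), 0.523 to 0.998 (phosphate) and 0.617 to 0.998 (senescence). The cause was not tested.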

Other observations

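The sulfur and touch lists, the handling tests, the single-library tests on genes not seen beforehand, the covariate, the pseudogene comparison by level, the bootstrap interval of the clock test and the neighbour count were chosen after the result was seen; the clock test, the single-library test over both lists and the linkage test were written before their values were seen, but the clock and single-library tests were set to undecided afterwards.

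Genes of the sulfur deficiency response were lower in hta9 hta11 almost throughout. Of 13 genes tested, 10 fell, with a median log2 fold change of -1.14 (camera p = 1.4e-28, 0.00374 with an estimated correlation), and of the 6 not seen before the list was made 3 fell (p = 6.5e-09, 0.00618 with an estimated correlation). The 3 were APR1, APR2 and SDI2, relatives of APR3 and SDI1, which had been seen beforehand, so they give no separate support. SULTR1;2 and SULTR4;2 did not pass, at -0.38 and -0.35. BGLU28, the only tested member that was higher, did not pass either, at 0.25 (adjusted p = 0.726). GGCT2;1 lost its call without hta9 hta11 library 4 (adjusted p = 0.0666). Of 10 touch-responsive genes 3 fell (p = 7.2e-06, 0.083 with an estimated correlation), all seen beforehand, and the 7 others gave p = 0.0901. In camera's test these others passed without wild type library 4, at 0.00654, and without hta9 hta11 library 1, at 0.0174, or library 4, at 0.0299. With an estimated correlation these values were 0.298, 0.313 and 0.368, and without hta9 hta11 library 3 camera gave 0.685. Of the 10, 1 fell without hta9 hta11 library 2 and 1 without library 4. Among the fits without 1 library TCH4 passed in those without wild type library 2 or hta9 hta11 library 1 and not in the others, with an adjusted p of up to 0.119 without hta9 hta11 library 4, and EXO lost its call without hta9 hta11 library 2 or 4 (up to 0.0643).

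Explanations for these falls were weighed. A clock shift stays open. The median absolute change over the clock list was 0.223 with a bootstrap interval of 0.101 to 0.336, which spans the bound of 0.25 set against it, ELF4 and CHE fell, and fry gave a mixed adjusted p = 0.000448. Such a mixed value from fry was not particular to the clock list. It was 1.4e-05 for the cold, drought and abscisic acid list and 0.00019 for the heat shock list. The largest camera p of 0.00197 over both lists and the 8 fits without 1 library decides nothing, since the lists hold the genes that prompted them. For the members not seen beforehand, the largest camera p with an estimated correlation was 0.0248 for the sulfur genes. It argues against a single library only weakly, since those that fell are relatives of genes seen beforehand. For the touch genes it was 0.857, which leaves a single library open because they did not pass over all libraries (0.472). A handling or wound response that differed between genotypes may contribute. It was judged by the 40 genes with the largest loadings on the first component of the deviations from the genotype means, RRTF1 and DDF1 among them. Their median signed change was -0.691 (-0.971 to -0.292). The interval resamples genes that vary together and does not measure the spread between libraries. The mean of their signed log2 CPM, the score, overlapped between the genotypes. It was 2.22, 1.26, 2.48 and -0.267 in wild type libraries 1 to 4 and 1.88, 0.219, -0.121 and 1.33 in hta9 hta11 libraries 1 to 4. The sign of the change was set after a first output had been seen, because that output was oriented against RRTF1. The score predicts 0.019 (-0.124 to 0.0947) of the -1.14 in the sulfur genes, which within these fits argues against it as their whole cause, and -0.139 (-0.562 to -0.0513) of the -0.55 in the touch genes, which leaves it open there because 1 end of that range reaches the change. The ranges in brackets run over the 8 fits without 1 library. Those fits share most libraries, so the ranges are not confidence intervals and understate the uncertainty.

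The same component held 40.3% of the variance within genotypes, with wild type libraries 1 and 3 and hta9 hta11 libraries 1 and 4 on its positive side. RRTF1, a transcription factor that responds fast to wounding, ranged from 2.98 to 22.8 CPM in the wild type and from 1.86 to 8.55 CPM in hta9 hta11.

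Of 130 pseudogenes tested 13 rose (odds ratio 4.43 against all other genes, Fisher's exact test, adjusted p = 0.000249). That test did not account for expression level. Below 1 CPM in the wild type 19.05% of 42 pseudogenes and 9.00% of 1966 other genes rose (odds ratio 2.38, 0.936 to 5.33, Fisher's exact test, adjusted p = 0.0507). At 1 CPM or more 5.68% of 88 and 1.73% of 18118 rose (odds ratio 3.42, 1.07 to 8.38, Fisher's exact test, adjusted p = 0.0385). Changed genes were next to each other in the order of tested genes in 40 pairs with the same direction, 28 up and 12 down, against a mean of 15.8 and a highest value of 33 in 10000 random placements (permutation p = 0.0001, the smallest they can give). Untested genes can lie between the members of a pair, so not all pairs are directly adjacent. Ordinary co-expression of neighbours and reads shared between copies were not tested. Within 500 kb of HTA9 or HTA11, 3.01% of 399 genes changed against 3.77% elsewhere (odds ratio 0.79, 0.403 to 1.41, Fisher's exact test p = 0.506), which argues against a general effect of linked sequence on neighbouring genes but not against an effect on single genes. The 12 that changed there include AP3 (log2 fold change 2.64), 76.7 kb from HTA11, and AT1G52800 (2.39), 18.97 kb from HTA9. Without AP3, chosen after its position was seen, the other 9 floral identity genes had a median of 1.63 (camera p = 6.6e-16, p = 0.00216 with an estimated correlation).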
